A study of Mus musculus with 30 samples.

How the data were processed

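Heavy chain (IgHM) sequencing of sorted peripheral blood B cells gave 30 libraries from 8 mice. These were Tom+ and Tom– cells at time points 1 and 2 of 6 TCL-1 mice (4 given tamoxifen at 50 mg/kg on postnatal day 10, and 2 on day 19) and of WT mouse 85, and at time point 2 of WT mouse 83. Per the labels, cells were lysed in RNAzol or a nucleic acid shield, total RNA was reverse transcribed with template switching, IgHM transcripts were captured through the constant region, and libraries were indexed with Nextera XT. Each deposited file lists 1 read per line with its V, D and J gene, junction, N and P lengths and V identity, and counts were made here from the lines. In the deposited tables V identity is a fraction per read, the share of V positions identical to the germline gene assigned by the authors, and was multiplied to percent. The aligner, germline release and read filters of the authors are not stated. The tables held productive reads only (100% in each library), no copy number and no molecular identifier. The 2 libraries of mouse 83 lacked V identity and N lengths and came from another sequencing run, so measures of N nucleotides and mutation cover 28 libraries. The Tom– library of mouse 91 at time point 1 held 0 clonotypes under 5 reads, unlike the other TCL-1 libraries, for a reason that is not stated. Its clonotype counts at time point 1, and its Tom– change over time, are therefore not fully comparable.

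Where a read listed several V genes (0.00612% to 7.78% of reads per library), the gene listed first was used, without its allele. A clonotype was a V gene, J gene and junction amino acid sequence with at least 2 reads, and shares of clonotypes are of the reads in such clonotypes. CDR3 sequences are printed without the conserved residues at both ends of the junction. Each library was described by 6 measures: the share of the largest clonotype, the effective number of clonotypes (inverse Simpson, log2), the share of clonotypes with Ighv11-2 or Ighv12-3, the share without N nucleotides at both junctions, the mean CDR3 length, and the share under 98% V identity. The last 4 count each clonotype once. Depth ran from 23080 to 1578030 reads per library. Shares of single libraries carry 95% exact Clopper-Pearson intervals and a count of 0 was taken to allow 3 counts. Neither covers variation between molecules or animals.

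Tom+ and Tom– libraries, and the time points, were compared within mice by two-sided exact sign-flip tests over the 64 sign patterns of 6 mice (smallest p 0.0312), with Benjamini-Hochberg adjustment over the 6 measures of a comparison. TCL-1 against WT and day 10 against day 19 mice were compared at time point 2 by two-sided exact permutation tests over the 15 splits of 4 against 2 (smallest p 0.0667). J and D genes with a mean share of at least 1% were tested like the measures. Clonotypes shared between libraries were measured as the Morisita-Horn overlap of nucleotide clonotypes, with a one-sided exact permutation of the mouse assignment.

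The number of clonotypes per V gene was compared with limma 3.58.1 (voom weights, empirical Bayes moderation, mouse as block where paired) under R 4.3.3, after a filter (a count of 10 at the median library size in as many libraries as the smaller group has, and a total of 15) and with trimmed mean of M values (TMM) scaling over the genes past the filter (trims 0.3 and 0.05), at an adjusted p threshold of 0.05. TMM and the filter were computed by hand-written code. limma took the place of the negative binomial test chosen at first, for which no software was at hand. V gene families were tested in the same way, unfiltered, with total clonotypes as library size. On simulated counts with 20 changed genes and the depth of these libraries, 20 simulations each, 82.7% to 100% of the changed genes that passed the filter were called, but 11.8% to 44.3% of the genes called were unchanged. Of these, 1 was called higher and 151 lower. With the true scaling given, 3.06% to 10.1% of the genes called were unchanged. Lower calls are therefore relative to the genes that rose. The simulated Tom+ counts started from the Tom– composition, with a dispersion of 0.2 and no variants of dominant clonotypes. A mean of 14.85 to 26.25 genes passed the filter there, against 12 and 11 in the real fits. These rates therefore need not hold for the real libraries.

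Before the data were examined, the rule for named genes was fixed as follows: every V gene of the fixed lists (phosphatidylcholine Ighv11-2 and Ighv12-3; phosphorylcholine Ighv7-1; other B-1a genes Ighv6-6, Ighv1-53, Ighv1-55, Ighv2-6-8 and Ighv9-3; anti-thymocyte Ighv8-12; D-proximal Ighv5-2) and the V gene families as sums. Also named were the 5 V genes with the largest log2 fold change in each direction at each time point among those past the threshold and in the same direction in 6 of 6 mice. The rule further took the largest clonotype of each TCL-1 library at time point 2 and of any library with a clonotype over 20%, and the CDR3 sequences fixed for Ighv11-2, Ighv12-3 and Ighv7-1. Other clonotypes named were chosen after their values were seen.

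Alternatives fixed at the same time changed the clonotype definition (nucleotide, or with 1-mismatch variants merged into a clonotype 10 times as abundant), the minimum number of reads (1 or 5), reads against distinct sequences, depth (libraries thinned to the smallest), weighting by reads, the scaling, the filter, the mouse block, the N and V identity limits, the diversity and overlap index, and the mice included. Alternatives chosen after seeing the data merged variants of up to 3 mismatches into a clonotype 20 times as abundant, left out reads with adapter sequence in the V region, left out mice 95 and 97, and changed the set of genes or the method of scaling. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 was used for the rest.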

Results

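Heavy chain repertoires of IgM-expressing B cells were read from peripheral blood of 8 mice that carried a tamoxifen-induced tomato mark. CD19+ B cells that were tomato-positive (Tom+, made early in life, when the mark was given on postnatal day 10 or 19) and tomato-negative (Tom–, unmarked) were sorted from the same blood sample. Tom– cells stand for B cells made later, but how many early cells escaped the mark was not measured. The Eµ-TCL-1 transgene, which drives a leukaemia resembling human chronic lymphocytic leukaemia, was carried by 6 mice: mice 86, 94, 95 and 97, marked on day 10, and mice 90 and 91, marked on day 19. Each was sampled in both populations at time points 1 and 2. Mice 85 and 83, marked on day 10, were wild-type (WT) controls; mouse 83 was sampled at time point 2 only. The 30 libraries held 4283906 productive reads, from 23080 to 1578030 per library with a median of 89452. They gave 216 to 4657 clonotypes per library, where a clonotype is a V gene, J gene and CDR3 amino acid sequence with at least 2 reads. Reads carried no molecular identifiers, so intervals on shares and limits on undetected items cover counting error only. All 28 libraries of the other mice came from 1 sequencing run and the 2 libraries of mouse 83 from another.

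The first question was whether single clonotypes dominate the Tom+ libraries of TCL-1 mice more than their Tom– libraries. Shares within each sorted population do not show which of them grew in number. A large Tom+ clonotype was also seen in WT mouse 85 (76.0% and 81.6% at time points 1 and 2), though not in WT mouse 83 (11.6%). In every TCL-1 mouse, 1 clonotype filled much of the Tom+ library while the Tom– library of the same blood was diverse, except in mouse 91 at time point 2, where the largest Tom– clonotype held 52.6% of reads and the effective number of clonotypes (log2) was 1.85. At time point 1 the largest clonotype held 67.9% ± 17.2 (SD, n = 6) of the reads in Tom+ and 2.74% ± 3.51 in Tom–. At time point 2 the shares were 65.1% ± 20.4 and 10.1% ± 20.8. The effective number of clonotypes (inverse Simpson index, log2) was 1.00 ± 0.54 in Tom+ and 8.13 ± 0.98 in Tom– at time point 1, and 1.08 ± 0.68 and 7.78 ± 3.42 at time point 2. In 6 of 6 mice at each time point the largest share was higher and the effective number lower in Tom+. The mean differences were 65.1 percentage points and −7.12 log2 units at time point 1, and 55.0 points and −6.70 units at time point 2. Each of these differences had p = 0.0312 in a two-sided exact sign-flip test, the smallest that 6 pairs allow, with adjusted p of 0.0375 at time point 1 and 0.0469 at time point 2 over 6 measures (exact test, n = 6).

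**Figure D1:**
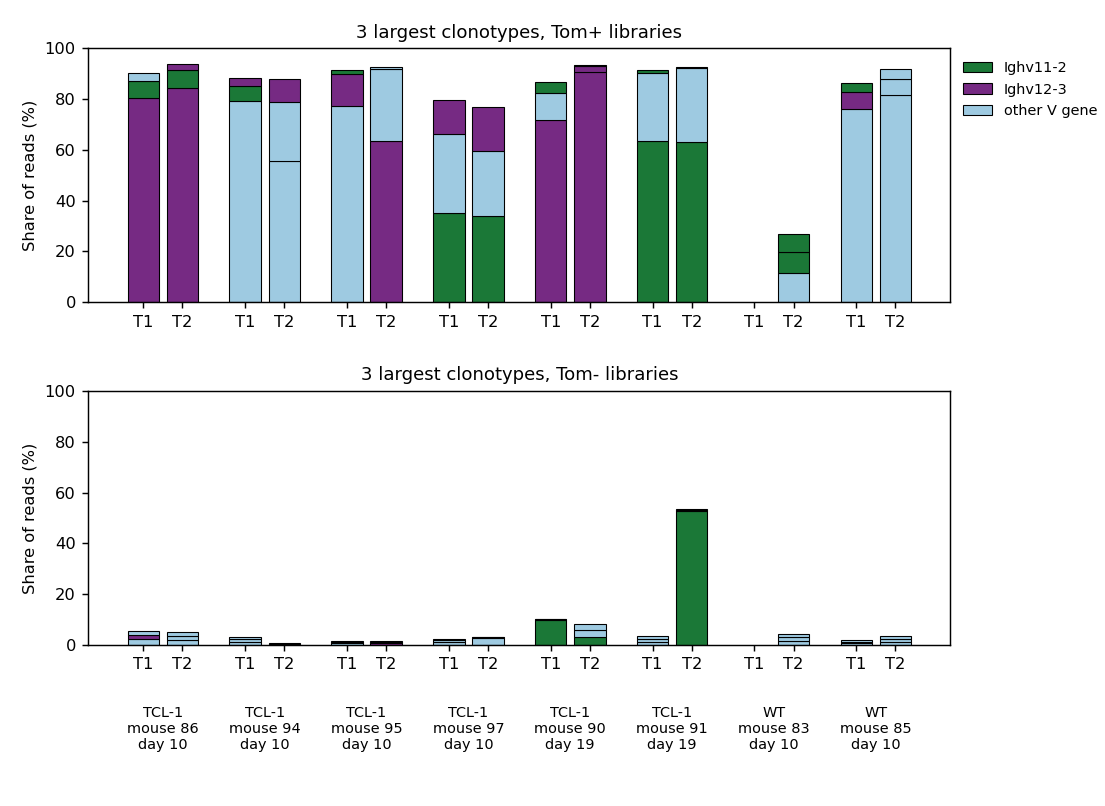
The 3 largest clonotypes of each library as a stacked share of its reads (%), by mouse and time point, with Tom+ and Tom– libraries in separate panels. The largest Tom+ clonotypes of TCL-1 mice held 33.8% to 90.6% of reads at time point 2, and among the TCL-1 Tom– libraries only that of mouse 91 at time point 2 had a clonotype above 20%, at 52.6%.

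Most of these dominant Tom+ clonotypes used Ighv12-3 or Ighv11-2, the V genes of B-1 cells that bind phosphatidylcholine: 4 of 6 at time point 1 and 5 of 6 at time point 2. In mouse 86 Ighv12-3 with Ighj1 and CDR3 AGDYDGYWYFDV held 80.4% of reads at time point 1 and 84.2% at time point 2 (95% exact Clopper-Pearson interval 83.9% to 84.5%, as for the other intervals here). In mouse 90 Ighv12-3 with Ighj1 and AGDSDGYWYFDV held 71.6% and then 90.6% (interval 90.3% to 90.8%). In mouse 91 Ighv11-2 with Ighj1 and IYYGPYWYFDV held 63.5% and 63.1% (interval 62.8% to 63.4%), and beside it was Ighv1-55 with Ighj1 and ARRDYYGSYWYFDV at 26.9% and 29.3%. In mouse 97 Ighv11-2 with Ighj1 and MRYSNYWYFDV held 35.1% and 33.8% (interval 33.6% to 34.1%). Ighv7-1, the V gene of phosphorylcholine-binding antibodies, with Ighj3 and ARDAWFAY, held 31.2% and 25.7%. The dominant clonotype of mouse 94 used Ighv5-9-1 with Ighj4 and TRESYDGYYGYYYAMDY, at 79.2% and then 55.6% (interval 55.3% to 55.9%). Ighv9-3 with Ighj2 and ARELYFDY stood there at 2.21% and then 23.1%. In mouse 95 Ighv5-9 with Ighj2 and ARHDYYGSSYYFDY held 77.4% at time point 1 and 28.4% at time point 2. Ighv12-3 with Ighj1 and AGDSWGYWYFDV went from 12.5% to 63.5% (interval 63.3% to 63.8%). The largest Tom+ clonotype had a V identity of 100% in 6 of 6 mice and no N nucleotides in 4 of 6 at each time point. In Tom– at time point 2 the largest clonotype of mouse 91 was again Ighv11-2 with Ighj1 and IYYGPYWYFDV (52.6%, interval 52.3% to 52.9%). The others were smaller: Ighv11-2 with Ighj1 and MRYGNYWYFDV in mouse 90 (3.0%), Ighv1-53 with Ighj3 and ARSRGYYDWFAY in mouse 97 (2.55%) and Ighv3-6 with Ighj1 and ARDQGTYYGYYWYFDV in mouse 86 (1.87%). Mouse 95 had Ighv12-3 with Ighj1 and AGDSWGYWYFDV (0.554%) and mouse 94 had Ighv3-6 with Ighj4 and ASIARGYAMDY (0.313%).

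Counting each clonotype once, the phosphatidylcholine genes Ighv11-2 and Ighv12-3 together made up 47.3% ± 19.0 (SD, n = 6) of Tom+ clonotypes and 2.17% ± 2.23 of Tom– clonotypes at time point 1, and 63.3% ± 29.3 and 4.60% ± 6.38 at time point 2. Clonotypes without N nucleotides, which terminal transferase adds little of before birth, made up 31.0% ± 16.9 of Tom+ and 4.66% ± 0.88 of Tom– clonotypes at time point 1, and 33.6% ± 21.7 and 4.27% ± 1.49 at time point 2. Both shares were higher in Tom+ in 6 of 6 mice at time point 1 (exact sign-flip test, p = 0.0312, adjusted p = 0.0375), and so was the first at time point 2 (exact test, adjusted p = 0.0469). The share without N nucleotides did not pass at time point 2, where it was higher in 5 of 6 mice (exact p = 0.0625, adjusted p = 0.075). Mean CDR3 length was 12.6 ± 1.53 amino acids in Tom+ and 12.2 ± 0.149 in Tom– at time point 1 (exact p = 0.62, n = 6), and 12 ± 1.01 and 12.1 ± 0.226 at time point 2 (exact p = 0.781). Many Tom+ clonotypes differed by few bases from dominant ones. Merging variants of up to 3 mismatches, an alternative chosen after seeing the data, left 11 of the 346 nucleotide clonotypes of mouse 86 Tom+ at time point 2. The excess of the phosphatidylcholine genes at time point 1 was then 26.0 percentage points instead of 45.2, and still passed (exact test, adjusted p = 0.0312). With that merging the CDR3 difference at time point 1 turned to −0.602 amino acids and passed (exact test, adjusted p = 0.0312). Weighted by reads, the excess without N nucleotides at time point 1 was 54.8 points instead of 26.3 and no longer passed (exact test, adjusted p = 0.075).

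**Figure D2:**
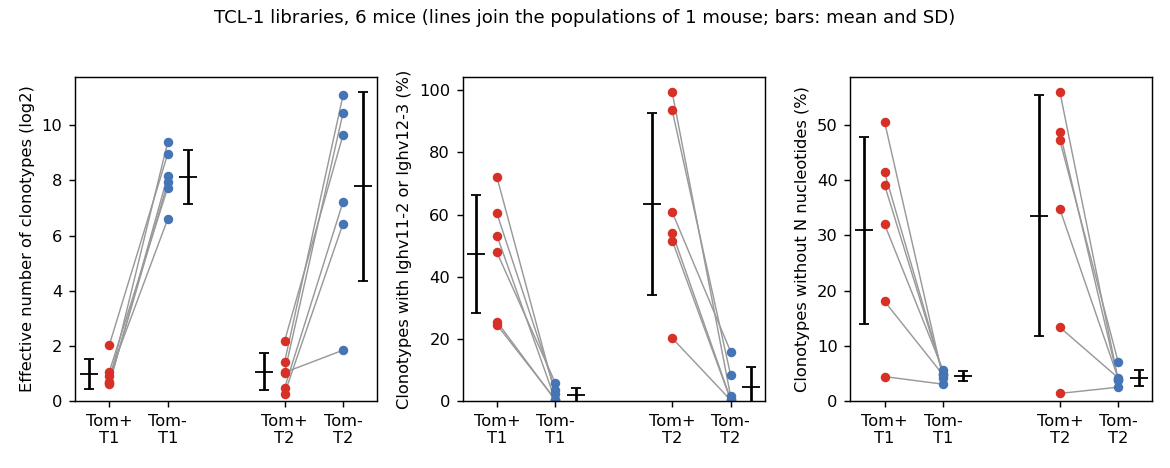
Effective number of clonotypes (log2), share of clonotypes with Ighv11-2 or Ighv12-3 (%) and share of clonotypes without N nucleotides (%) in the Tom+ and Tom– libraries of the 6 TCL-1 mice at time points 1 and 2; lines join the populations of 1 mouse, bars give mean and SD. Tom+ had the higher share of the phosphatidylcholine genes in 6 of 6 mice at each time point, and the higher share without N nucleotides in 6 of 6 and 5 of 6.

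Clonotypes with a V region under 98% identical to germline made up 39.5% ± 4.45 (SD, n = 6) of Tom+ and 14.9% ± 5.03 of Tom– clonotypes at time point 1, and 44.4% ± 2.92 and 22.0% ± 5.97 at time point 2 (higher in 6 of 6 mice, exact sign-flip p = 0.0312, adjusted p = 0.0375 and 0.0469). At time point 1 the Tom– library of mouse 91, which held 0 clonotypes under 5 reads, had the lowest share (7.79%). Its pair had the largest difference (38.1 percentage points), and without mouse 91 the mean difference was 21.8 instead of 24.6. Weighted by reads the direction turned, to −3.07 percentage points at time point 1 and −9.61 at time point 2 (exact p = 0.0312). The latter was enlarged by the Tom– libraries of mice 95 and 97. These had 23.5% and 23.8% of reads under 98%, against 2.30% to 7.73% in the other TCL-1 mice. In the 4 libraries of mice 95 and 97 at time point 2, a mean of 16.9% of reads had template-switch adapter sequence inside the aligned V region, against 0.282% to 5.14% in the other 24 libraries with V identities.

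V gene by V gene, Ighv12-3 and Ighv11-2 were the genes that rose in Tom+ at time point 1 (limma, 12 genes past the filter on low counts). Ighv12-3 rose by a log2 fold change of 6.43 (SE 1.26, adjusted p = 4.24e-05), from 0.357% ± 0.424 (SD, n = 6) of Tom– clonotypes to 24.1% ± 21.9 of Tom+ clonotypes, and was higher in 6 of 6 mice. Ighv11-2 rose by 5.70 (SE 1.22, adjusted p = 9.75e-05), from 1.82% ± 2.36 to 23.2% ± 15, in 6 of 6 mice. With junction variants merged and no filter both stayed called, at smaller log2 fold changes of 3.28 for Ighv12-3 and 4.40 for Ighv11-2. They also stayed called without any 1 mouse, at log2 fold changes down to 4.18 for Ighv12-3 (without mouse 86) and 3.39 for Ighv11-2 (without mouse 97). Another 5 genes, Ighv3-6, Ighv5-4, Ighv6-3, Ighv1-64 and Ighv1-26, fell in 6 of 6 mice, with log2 fold changes from −3.33 to −2.94 and adjusted p of 0.0214 to 0.0231. Ighv3-6, for example, made up 0.539% ± 0.632 of Tom+ and 5.88% ± 1.08 of Tom– clonotypes. With variants merged and no filter their log2 fold changes were smaller, between −1.78 and −1.29, and Ighv1-64 was no longer called (adjusted p = 0.0560). These lower calls are relative shares: without mouse 90, without mouse 94, and without mice 95 and 97 together their number was 0, and without mouse 97 it was 1. With total clonotypes as library size 2 genes were higher and 9 lower, and the median log2 fold change of the tested genes was −3.16 instead of −2.24 (at time point 2, −3.37 instead of −3.50).

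At time point 2 the same genes rose (limma, 11 genes tested). Ighv12-3 had a log2 fold change of 5.84 (SE 1.07, adjusted p = 0.000647), with 42.3% ± 37.4 (SD, n = 6) of Tom+ and 0.423% ± 0.344 of Tom– clonotypes, and was higher in 6 of 6 mice (2.60 with variants merged and no filter, adjusted p = 0.00415). Ighv11-2 had a log2 fold change of 3.08 (SE 0.98, adjusted p = 0.0147), with 21% ± 22.5 and 4.18% ± 6.25, and was higher in 5 of 6 mice. The 7 genes that fell included Ighv3-6 (−4.97), Ighv1-26 (−4.62), Ighv14-2 (−3.91) and Ighv1-72 (−3.63). Each was lower in 6 of 6 mice, with adjusted p of 0.000289 to 0.00199. Ighv14-4 also fell (adjusted p = 0.000289). It had 0 of 2709 Tom+ clonotypes, against 404 of 16199 Tom– clonotypes over the group. Many Tom+ clonotypes were near-copies of dominant ones, so the 0 sets no firm limit on the share. With variants merged and no filter its log2 fold change was −2.90 instead of −4.50 (limma, adjusted p = 0.0023). The call for Ighv11-2 was lost without mouse 91 (log2 fold change 1.59, adjusted p = 0.383), without mouse 86 (1.87, adjusted p = 0.124) and without mouse 97 (2.27, adjusted p = 0.0787). It was also lost in the 4 day 10 mice alone (1.76, adjusted p = 0.133), without mice 95 and 97 (adjusted p = 0.220), without the filter (0.0579), without the mouse block (0.0625) and with TMM over all V genes (0.0534). Its adjusted p ranged from 0.00335 to 0.383 over its alternatives.

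Among the 10 V genes listed beforehand, the 2 phosphatidylcholine genes rose at both time points, and 2 is also the number that rose when adjusted over the list alone. Of the other B-1a genes, Ighv9-3 fell at time point 2 (log2 fold change −2.57, adjusted p = 0.0487, lower in 5 of 6 mice), but not when adjusted over the list alone (adjusted p = 0.0532), nor with total clonotypes as library size, without the mouse block, by reads, from 1 read or with TMM over all V genes. Its change of −1.85 at time point 1 did not pass (adjusted p = 0.148), but did with total clonotypes, by nucleotide clonotypes, and without mouse 86 or 91, and it turned to 0.37 in the day 10 mice. Ighv1-53 narrowly did not pass at time point 1 (−2.58, adjusted p = 0.0511), and it was called lower under 8 alternatives, with adjusted p down to 2.46e-07 (without mouse 86). Ighv1-55 did not pass at time point 1 (1.26, adjusted p = 0.335; −1.41 without mouse 91) or time point 2 (−0.53, adjusted p = 0.620; −5.51 and called in the day 10 mice), and it had no stable direction. The rest were too rare to test. Ighv6-6 made up 1.58% ± 3.17 (SD, n = 6) of Tom+ and 1.92% ± 0.921 of Tom– clonotypes at time point 1, and Ighv2-6-8 was absent from the files. Ighv7-1 made up 4.64% ± 11 and 0.346% ± 0.328, and held 33.8% of Tom+ reads in mouse 97. Ighv8-12, the anti-thymocyte gene, made up 0.104% ± 0.254 and 1.94% ± 0.402 at time point 1, and 0% (0 of 2709 clonotypes) and 1.59% ± 0.665 at time point 2, lower in 6 of 6 mice each time. Ighv5-2, a D-proximal gene used early in ontogeny, made up 0.131% ± 0.186 and 0.381% ± 0.390 at time point 1.

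By family, Ighv11 and Ighv12 rose at both time points (limma, adjusted p from 9.94e-07 to 0.0386). Their log2 fold changes were 4.48 and 5.26 at time point 1, and 2.75 and 6.0 at time point 2. Ighv12 rose under every scaling, whereas Ighv11 at time point 2 did not with TMM (adjusted p = 0.231). The remaining families called were lower in Tom+, 12 at time point 1 and 8 at time point 2, of 15 families tested. The Ighv1 family, the largest of the mouse, made up 17.5% ± 15.9 (SD, n = 6) of Tom+ and 48.9% ± 4.33 of Tom– clonotypes at time point 1, and 10.1% ± 13.5 and 52% ± 11 at time point 2. The lower calls mostly ended with junction variants merged. At time point 1 only Ighv11, Ighv12 and Ighv8 stayed called, and the direction flipped, uncalled, for Ighv2, Ighv4, Ighv7, Ighv13 and Ighv15. At time point 2 only Ighv14 stayed called lower (adjusted p = 0.0103), while Ighv1, Ighv3, Ighv5, Ighv8, Ighv9 and Ighv10 were lower but uncalled. The direction flipped there for Ighv2, Ighv4, Ighv6, Ighv7, Ighv13 and Ighv15. Of these, Ighv2, Ighv4, Ighv13 and Ighv15 passed with positive fold changes (limma, adjusted p from 5.13e-05 to 0.0103). These cannot be read as a rise, since Ighv15 made up 0% of Tom+ clonotypes. Merged Tom+ libraries held 11 to 61 clonotypes, against 122 to 3916 in Tom–. The constant that voom adds to each count then weighs more in Tom+. Merging therefore cannot decide whether the lower calls of rare families hold. With TMM in place of total clonotypes the median log2 fold change of the 15 families moved from −2.05 to −1.21 at time point 1 and from −2.55 to −4.53 at time point 2. The calls were then 2 higher and 2 lower at time point 1 and 1 higher and 13 lower at time point 2.

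The J gene Ighj1, which encodes the WYFDV ending of the phosphatidylcholine CDR3s, made up 58.9% ± 27.9 (SD, n = 6) of Tom+ and 18.7% ± 3.75 of Tom– clonotypes at time point 1, and 71.6% ± 31.8 and 20% ± 5.36 at time point 2, higher in 6 of 6 mice each time. After adjustment it did not pass (exact sign-flip p = 0.0312, adjusted p = 0.12 and 0.0625), nor did any other J or D gene. With variants of up to 3 mismatches merged, Ighj1 (higher), Ighj3 (lower) and Ighj4 (lower) passed at time point 2 (exact test, adjusted p = 0.0417). At time point 1 Ighv11-2 with MRYGNYWYFDV or MRYSNYWYFDV and Ighv12-3 with AGDYDGYWYFDV each had reads in 6 of 6 TCL-1 Tom+ libraries, with highest shares of 6.60% in mouse 86, 35.3% in mouse 97 and 80.8% in mouse 86, and in 2, 3 and 3 of the 6 Tom– libraries. They exceeded 1% of Tom+ reads in 3, 3 and 2 mice. In the other 4 mice AGDYDGYWYFDV had 3 to 73 reads, and MRYSNYWYFDV had 12 reads in mouse 91, too few to tell from carry-over between libraries. Each was in 5 of 6 Tom+ libraries at time point 2, above 1% in 1, 2 and 2 of them, and in 2, 4 and 3 Tom– libraries. In mouse 90 MRYGNYWYFDV was higher in Tom–, at 9.84% against 4.35% in Tom+ at time point 1. At time point 2 it was 3.01% against 0.635% there. It was higher in Tom+ in the other TCL-1 mice, except mouse 95 at time point 2, with 0 reads in both populations. Ighv11-2 with MRYGSSYWYFDV was in 2 of 6 TCL-1 Tom+ libraries at time point 1 (highest 0.206%) and in 0 of 6 at time point 2. Ighv12-3 with AGDRYGYWYFDV was in 2 of 6 at time point 1 (highest 0.319%) and in 2 of 6 at time point 2 (highest 0.221%). In WT mouse 83 the Tom+ library held MRYGNYWYFDV at 8.38%, MRYGSSYWYFDV at 6.89% and AGDYDGYWYFDV at 5.37%. The phosphorylcholine sequence ARDYYGSSYWYFDV with Ighv7-1 was detected in 0 of 30 libraries, which allows shares of up to 0.000192% to 0.0130%.

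A further comparison asked whether the repertoires moved between the time points. Persistence was measured as the Morisita-Horn overlap of nucleotide clonotypes (0 for none shared, 1 for identical). Tom+ repertoires of 1 mouse overlapped across time points by 0.911 ± 0.166 (SD, n = 7) and those of different mice by 0.0171, and Tom– repertoires by 0.0760 ± 0.106 and 0.000462. In both populations the overlap within mice exceeded that between mice (one-sided exact permutation of the mouse assignment, p = 0.000198, the smallest that 5040 assignments allow). The high Tom+ value rests on the abundant clonotypes: by the Jaccard index, which ignores abundance, the excess within mice was 0.259 instead of 0.894 (exact permutation, p = 0.000198). The Tom– overlap was highest in mice 90 (0.264), 97 (0.177) and 86 (0.0835), and without mouse 90 the Tom– excess was 0.0444 instead of 0.0755. By the Jaccard index the Tom– excess was 0.00441 and mouse 91 was highest (0.0141). In 5 of 6 TCL-1 mice the largest Tom+ clonotype was the same at both times, and mouse 95, where Ighv12-3 with AGDSWGYWYFDV overtook Ighv5-9 with ARHDYYGSSYYFDY, had the lowest overlap of 0.542. On average over mice no measure differed past the threshold. From time point 1 to 2 the largest Tom+ share differed by −2.74 percentage points ± 14.7 (exact sign-flip p = 0.656, n = 6). The share of the phosphatidylcholine genes among Tom+ clonotypes differed by 16 points ± 16.2 (exact p = 0.12, adjusted p = 0.25). In Tom– the largest share differed by 7.40 points ± 21.7 (exact p = 0.812, n = 6), a value made by mouse 91, without which it was −1.38. None of the 6 measures passed in either population. The test of the change in Tom+ against that in Tom– gave −10.1 points for the largest share (exact p = 0.469, n = 6; −1.82 without mouse 91, −17.3 without mouse 90) with no measure past the threshold.

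Overlap between the Tom+ and Tom– libraries of 1 mouse was low but above that between mice at time point 1, at 0.00936 ± 0.0142 (SD, n = 7) against 0.00151 (one-sided exact permutation, p = 0.00238). Without mouse 86 that difference fell from 0.00785 to 0.00378, and mice 95 and 97 lay below their median against other mice. At time point 2 it was 0.118 ± 0.308 (n = 8) against 0.00233 (exact permutation, p = 0.0185), and this rested on mouse 91: its overlap was 0.879, and without it the difference was 0.00682 (exact permutation, p = 0.148). The shared clonotype of mouse 91 was Ighv11-2 with IYYGPYWYFDV, at 0.182% of Tom– reads at time point 1 and 52.6% at time point 2. At smaller shares, the dominant AGDYDGYWYFDV clonotype of mouse 86 held 1.52% of Tom– reads at time point 1, and AGDSDGYWYFDV of mouse 90 held 1.16% at time point 2. The Tom+ and Tom– libraries of 1 mouse and time point always carried the same first index. Up to 87.0% of the clonotypes of a Tom– library (those of at least 5 reads) were found, at any share, in a library of another mouse with that index. The excess at time point 1 is therefore not separated from carry-over. In WT mouse 85 at time point 1, 543 of the 1042 Tom+ nucleotide clonotypes were also in the Tom– library, but 34.7% of the clonotypes of that Tom– library with at least 5 reads were found in the Tom– and 15.4% in the Tom+ library of mouse 86.

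**Figure D3:**
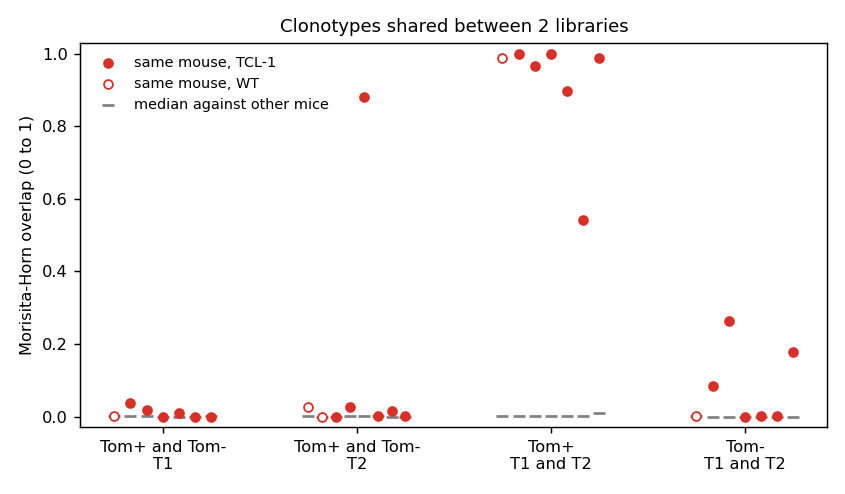
Morisita-Horn overlap (0 to 1) between the Tom+ and Tom– libraries of 1 mouse at time points 1 and 2, and between time points for Tom+ and for Tom–; filled points are TCL-1 mice, open points WT mice, and grey dashes the median against other mice. Tom+ libraries of 1 mouse overlapped across time by 0.542 to 0.999, and at time point 2 the populations of mouse 91 overlapped by 0.879.

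The WT mice served as the background for the TCL-1 transgene, among day 10 mice at time point 2. Large Tom+ clonotypes were also found in WT: mouse 85 had Ighv2-2 with Ighj4 and ARNGYYYAMDY at 76.0% of Tom+ reads at time point 1 and 81.6% (interval 81.3% to 81.9%) at time point 2, whereas the largest of mouse 83, Ighv1-64 with Ighj2 and VRRGVTLFDY, held 11.6%. The largest Tom+ share was 59.3% ± 20.8 (SD, n = 4) in TCL-1 and 46.6% ± 49.5 (n = 2) in WT (two-sided exact permutation, p = 0.667). Ighv11-2 and Ighv12-3 made up 56.4% ± 32.5 of TCL-1 and 14.7% ± 18.3 of WT Tom+ clonotypes (exact permutation, p = 0.267, n = 4 and 2). In Tom– the largest shares were 1.32% ± 1.07 and 1.43% ± 0.211 (exact permutation, p = 1, n = 4 and 2), and the phosphatidylcholine genes 0.791% ± 0.571 and 1.82% ± 0.752 (exact permutation, p = 0.133). The smallest p that 4 against 2 mice allow is 0.0667, so no difference could pass. Mouse 83 came from the other sequencing run, and within the run shared by the others 1 WT mouse was left. Of 7 V genes tested in Tom+ with limma, 0 were higher and 3 lower in TCL-1. Ighv2-2 was lower by a log2 fold change of −7.07 (adjusted p = 0.0150), with 66.4% of clonotypes in mouse 85. Ighv1-26 (adjusted p = 0.0140) and Ighv10-3 (adjusted p = 0.0150) were found in 0 of 2008 TCL-1 Tom+ clonotypes, against 66 and 41 of 1863 in WT. Many of these clonotypes were near-copies of dominant ones, so the 0 sets no firm limit on the fold. The 3 calls ended (0 genes) without mouse 85, without mouse 94, 95 or 97, with total clonotypes as library size, or with junction variants merged and no filter. In Tom–, limma called 0 of 72 genes in either direction, with 11 at an unadjusted p under 0.05. Other scalings called up to 5 higher and 1 lower there, and without mouse 85 the counts were 15 higher and 6 lower.

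The last comparison set mice marked on day 10 against those marked on day 19, in TCL-1 at time point 2. In Tom+ the largest share was 59.3% ± 20.8 (SD, n = 4) in day 10 and 76.8% ± 19.4 (n = 2) in day 19 mice, and the phosphatidylcholine genes made up 56.4% ± 32.5 and 77.2% ± 23.1 of clonotypes (exact permutation, p = 0.4 for each, n = 4 and 2). With 1 of the day 19 mice left out, these differences of −17.5 and −20.8 points became −3.79 and −4.44 (without mouse 90) or −31.3 and −37.1 (without mouse 91). In Tom– the largest share was 1.32% ± 1.07 and 27.8% ± 35.1, the effective number of clonotypes (log2) 9.59 ± 1.69 and 4.14 ± 3.24, and the share of the phosphatidylcholine genes 0.791% ± 0.571 and 12.2% ± 5.33. Each of these Tom– differences had p = 0.0667, the smallest possible (exact permutation, n = 4 and 2), so none could pass 0.05. Without mouse 91 the difference in the largest share was −1.67 points instead of −26.5, in the effective number 3.16 instead of 5.45 and in the phosphatidylcholine genes −7.66 points instead of −11.4. Without mouse 90 they were −51.3 points, 7.74 and −15.2 points. With junction variants merged the difference in the phosphatidylcholine genes was −1.82 percentage points, and weighted by reads it was −31.5. The Tom+ difference of these genes turned from −20.8 to 10.5 points with variants merged.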

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

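Every test in this part was set up after the result it concerns was seen. A search for a mouse far from the others covered 28 sets of values and flagged 6. The sets were the 6 measures in each group of 4 day 10 TCL-1 libraries, and each overlap comparison over the TCL-1 mice. Chance gives about 1 in 20 for independent sets of normal values. Here the measures are related and the overlaps are strongly skewed, so that rate is only a rough guide.

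In mouse 91 at time point 2 the Tom+ and Tom– repertoires overlapped by 0.879, against 1.77e-08 to 0.0257 in the other 5 TCL-1 mice, because Ighv11-2 with IYYGPYWYFDV held 63.1% of Tom+ and 52.6% of Tom– reads. Tom+ cells or Tom+ library material in the Tom– library would bring the second Tom+ clonotype at 24.4% of reads, and 1 read (0.00101%) was found there, which argues against that source. A candidate explanation is 1 clone with both Tom+ and Tom– members, since 99% of the Tom– reads of this clonotype had the nucleotide junction of the Tom+ clonotype, including 4 N nucleotides. Whether unmarked members existed before the mark or lost it was not tested.

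Mutated dominant clones of early-life origin are argued against as the source of the larger Tom+ share of clonotypes under 98% V identity. Weighted by reads, the difference was −3.07 percentage points at time point 1 and −9.61 at time point 2 (exact sign-flip p = 0.0312 each). The latter was enlarged by the Tom– libraries of mice 95 and 97 (23.5% and 23.8% of reads, against 2.30% to 7.73% in the other 4), which hold much adapter sequence. With near-copies of dominant junctions merged, 13.1 and 16.8 points remained (exact p = 0.0312 each). Yet 94.0% and 95.9% of the nucleotide clonotypes under 98% in Tom+ were such copies, against 64.8% and 58.9% in Tom–, and copies past the merging limits could remain, so near-copies as a cause stay open. Near-copies were also most of the Tom+ clonotypes of any identity. At time point 2 merging left 11 to 61 nucleotide clonotypes per Tom+ library, of 264 to 734. The high percentages are therefore not particular to clonotypes under 98%. Clonotypes of few reads may carry the pattern: among clonotypes of at least 20 reads the difference was 1.79 ± 3.94 points (SD, exact p = 0.344, n = 6) and −1.71 ± 6.24 (exact p = 0.62, n = 6), the latter lowered by the Tom– libraries of mice 95 and 97 (23.0% and 22.5%, against 2.56% to 6.71% in the other 4), which hold much adapter sequence. Under 5 reads the shares at time point 2 were 68.7% in Tom+ and 29.1% in Tom–, and whether these are errors of amplification or rare mutated cells stays open.

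Adapter sequence inside the aligned V region is outside the main measurement. It was found in a mean of 16.9% of reads (11.3% to 19.2%) in the 4 libraries of mice 95 and 97 at time point 2, against 0.282% to 5.14% in 24 others. Reads under 90% V identity made up 16.3% ± 2.81 (SD, n = 4) of these libraries and 3.03% of the others. Without reads that hold the adapter this was 1.91% ± 0.446 and 1.41%, with 3 of the 4 libraries inside the range of the others, consistent with adapter aligned as part of the V gene. Mutation between the time points is argued against, since 3.76% of the excess was left.

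In Tom– at time point 1 mouse 86 had 2.23% of clonotypes with Ighv11-2 or Ighv12-3, against 0.35% to 0.601% in the other 3 day 10 mice. In Tom– at time point 2 mouse 94 had 10.7% of clonotypes under 98% V identity, against 23.7% to 25.3% in the other 3 day 10 mice. In Tom+ at time point 1 the largest clonotype of mouse 97 held 35.1% of reads, against 77.4% to 80.4% in the other 3, and its effective number of clonotypes (log2) was 2.04 against 0.62 to 0.70. Tom+ persistence in mouse 95 was 0.542, against 0.897 to 0.999 in the other TCL-1 mice.

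Other splits of the 12 TCL-1 libraries of a time point tested chance. Exchanging Tom+ and Tom– within mice, 1 of 32 splits, the real one, called as many V genes at time point 1 (7 against at most 5) and at time point 2 (9 against at most 1). The same held for families (14 against at most 0, and 10 against at most 6). This argues against chance, but 1 of 32 is the smallest share possible and was not adjusted over the counts. It does not test the scaling on which the lower calls depend. Drawn splits mix mice and so break the pairing by mouse that the test uses. Of these, 8 of 98 called as many V genes at time point 1 (7 against at most 10) and do not exclude chance by themselves. At time point 2 it was 1 of 95 (9 against at most 0), and for families 1 of 98 (14 against at most 10) and 1 of 95 (10 against at most 7). In these only the real split called as many, which argues against chance.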

How the results depend on the processing

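Of 917 values under alternatives, 823 were counted as kept. These stayed on their side of the threshold or within the spread (counts: within 1.5 times). For the measures, values with mice left out were scored by the SD between mice. A mean cannot move by 1 SD when 1 or 2 of 6 mice, or 1 mouse of 4 against 2, are left out. Those values were therefore kept by construction and say nothing about stability. Another 22 fell short of the threshold, 20 newly passed, 49 moved and 3 turned direction. A turn was counted only where a value passed the threshold. Uncalled values that changed sign can be among the 823, such as the Tom+ phosphatidylcholine difference between day 10 and day 19 mice (−20.8 to 10.5 points). Counts of calls were compared by number alone, so families that turned direction are not counted as turned. The merging of variants of up to 3 mismatches, the removal of mice 95 and 97, the removal of adapter reads and the TMM changes for families and over all V genes were chosen after seeing the data. The higher Tom+ share of the largest clonotype, its lower effective number and its higher share of the phosphatidylcholine genes passed under every alternative with 6 mice except, at time point 2, a minimum of 5 copies; 5 mice allow no exact p under 0.0625 and 4 none under 0.12. Unless stated, the cause of a change was not tested.

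At time point 1 the excess without N nucleotides was 33.9 points with 1-mismatch variants merged, 54.8 weighted by copies and 31.4 with at most 1 N nucleotide, none past the threshold. The excess under 98% V identity was −3.07 weighted by copies and 7.99 in thinned libraries, the latter not past it, and CDR3 length turned to −0.602, past the threshold, with variants of up to 3 mismatches merged. At time point 2 a minimum of 5 copies gave 55.2 for the largest share, −6.62 for the effective number, 56.6 for the phosphatidylcholine genes and 3.15 for V identity, none past the threshold. The first 3 stayed near their main values of 55.0, −6.70 and 58.7, with an adjusted p of 0.0625 (exact test). Weighted by copies V identity gave −9.61. The share without N nucleotides passed with variants merged (37.5) and, at 29.3, without the replicate block. Sharing at time point 2 was 0.00682 without mouse 91, and up to 0.133 without another.

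V genes higher in Tom+ at time point 1 (2) were 23 without the filter and 19 merged without it, and at time point 2 (2) were 51 and 47, 4 counted by copies, and 1 without the mouse block, with TMM over all genes, in the 4 day 10 mice, without mice 95 and 97, and without 86, 91 or 97 (1 to 2 without any 1 mouse). Both genes higher at time point 1 stayed called under each alternative there. The counts of 23, 19, 51 and 47 came without the filter, which lets in genes with few or no Tom+ clonotypes. Tom+ libraries held 216 to 664 clonotypes at time point 2, against 916 to 4480 in Tom–. The constant that voom adds to each count weighs more in the smaller libraries. Those counts therefore cannot be read as genes that rose. Genes lower at time point 1 (5) were 9 with total clonotypes, 38 by copies, 12 by nucleotide clonotypes, 2 in day 10 mice, 0 without mice 95 and 97, and 0 to 11 without 1 mouse (0 without 90 or 94, 1 without 97, 11 without 86 or 91). At time point 2 (7) they were 40 without the filter, 36 by copies, 13 from 1 copy, 14 in day 10 mice, 43 merged, and 7 to 14 without 1 mouse (14 without 86). Families called at time point 1 (14) were 3 merged and 4 with TMM. Fewer tested genes or mice account for part of this by construction.

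V genes lower in TCL-1 than WT Tom+ (3) were 0 with total clonotypes, 0 merged, and 0 to 3 without 1 mouse (0 without 85, 94, 95 or 97). In Tom– (0 higher, 0 lower) they were 2 higher and 1 lower with median of ratios, 5 and 1 with total clonotypes, 9 higher without the filter, and 0 to 15 higher and 0 to 6 lower without 1 mouse (15 and 6 without 85, which leaves 1 WT mouse assumed to vary like the TCL-1 mice).

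Not run: the authors' clone identifier (none deposited), non-productive sequences (none deposited) and a second count model. Median of ratios gave no value for Tom+ against Tom– or for TCL-1 against WT Tom+, since too few V genes were present in every library. The number of clonotypes, not of reads, limits the V gene tests: only 12 and 11 genes passed the filter because Tom+ libraries hold few clonotypes. Counted by copies, 63 and 54 genes passed it.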

Other observations

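Clones of other V genes accompanied the dominant ones. In Tom+ of mouse 90 at time point 1, Ighv1-15 with Ighj1 and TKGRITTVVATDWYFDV held 11% of reads, and 0.325% at time point 2. In WT mouse 85 Ighv12-3 with AGDSWGYWYFDV, the CDR3 that held 63.5% of Tom+ reads in mouse 95 at time point 2, held 6.84% of Tom+ reads at time point 1 and 0.00296% at time point 2. Of all Tom+ reads in clonotypes at time point 2, the phosphatidylcholine genes held 99.99% in mouse 86, 98.8% in mouse 90, 67.9% in mouse 91, 12.6% in mouse 94, 67.3% in mouse 95 and 56.0% in mouse 97, and 31.1% and 0.105% in WT mice 83 and 85. In Tom– they held 55.9% in mouse 91 and 8.41% in mouse 90. These clonotypes were chosen after their values were seen.

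In 11 of 14 Tom+ libraries from the main sequencing run, the most frequent single-base variant of the largest junction lay 24 bases before its last base, at 1.73% to 2.80% of the parent's reads, across junctions of 39 to 57 nucleotides. In the other 3 it lay elsewhere, at 0.555% to 0.646%, and in the other run 0 of 1 Tom+ library had it there. For 76 pairs of libraries of different mice that share the first index, a median of 0.294% of a Tom– library's clonotypes of at least 5 reads were found, at any share, in the other, up to 87.0%. For 36 pairs with the second index shared the median was 0.379%, up to 3.38%, and for 224 pairs with neither it was 0.134%, up to 4.51%.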
